A study of Homo sapiens with 21 samples.

How the data were processed

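RNA from 21 samples was measured on Illumina bead arrays, 1 array per sample. Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin. The design text calls the 3 samples of each group biological triplicates. The 7 groups are DiFi cells with DMSO, PHA-665752 or gefitinib, and GTL-16 cells with DMSO, PHA-665752, gefitinib or doxycycline. Treatment lasted 24 h, except for doxycycline, which lasted 48 h, and both inhibitors were used at 1 uM, per the labels. All GTL-16 samples carried an inducible MET shRNA vector, per the labels. No sample without that shRNA received doxycycline, and no DMSO sample was kept for 48 h.

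The table used here holds, for 20589 array features and each array, a signal intensity that the authors deposited without normalisation and a detection p-value, per the file headers. The submitters' processing notes name BeadStudio 1.5.1.3. Detection p-values lie on 708 equal steps, as ranks among negative controls do, except in 1441 features (7%), whose values look like means over several probes and whose detection p-value may not be a rank. The deposited series matrix holds a second intensity per feature and array, the authors' processed values. Each of its columns is a straight line of the same array's raw intensity (slope 0.704 to 1.63, largest residual 0.0556 to 0.131), which also checks that columns and samples match: the correlation with a column's own array was 1 and with any other array at most 0.998. Medians of these columns for replicates 1, 2 and 3 were 55.1, 57.7 and 57.7 (DiFi DMSO), 59.1, 59.2 and 59.6 (DiFi PHA-665752), 68.4, 65.9 and 65.1 (DiFi gefitinib), 56.6, 51.8 and 50.9 (GTL-16 DMSO), 61.1, 59.6 and 58.8 (GTL-16 PHA-665752), 53.6, 55.4 and 52.3 (GTL-16 gefitinib) and 67.8, 65.3 and 64.9 (GTL-16 doxycycline). The scale is linear, the columns are not centred, and the rule by which the slopes were chosen is not given in the sources used here. The raw signal was used, with the processed values as an alternative.

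Signals were background-corrected by normexp with the background mean and SD of each array inferred from the detection p-values, an offset of 16 was added, and arrays were quantile-normalised and put on the log2 scale, as the neqc method of limma does. One step departs from it: the background was fitted on features whose detection p-value lies on the 708 steps, since the fit needs p-values that fall steadily with signal, and then applied to all features. Background means were 104 to 141 and SDs 17.4 to 32.0. A feature was tested if its detection p-value was under 0.01 on at least 3 of the 21 arrays (11460 features). Gene symbols came from the platform's annotation: 18332 features have 1 symbol, 0 have several and 2257 have none. Of the former, 18315 matched a current gene by Entrez identifier and 0 symbols changed. The reference table is of assembly GRCh38.p14, used for names only, and no coordinates are given. The feature with the highest mean stood for each gene, which left 11030 genes, 10048 of them named and 982 features without a symbol, which are counted but not named. Where a gene had several tested features (416 genes), they were called in opposite directions for 7 genes in GTL-16 cells with PHA-665752, 8 with doxycycline and 7 in DiFi cells with gefitinib.

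Group means were fitted to all 21 arrays with limma (lmFit and eBayes, 14 residual and 4.29 prior degrees of freedom), so that all groups share 1 estimate of the spread. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Treatments were compared with DMSO of the same line, doxycycline with PHA-665752, the 2 lines under DMSO with each other (8422 genes called, 4139 higher and 4283 lower in GTL-16), and effects between lines by differences of differences. The on-target set holds genes called in the same direction with PHA-665752 and doxycycline in GTL-16 and gefitinib in DiFi cells and also against the control inhibitor of each line.

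Before the data were examined, 25 gene lists, the comparisons, the tests, the alternatives and the rule for named genes were fixed. That rule picked the 8 genes with the highest and the 8 with the lowest change in the 3 on-target comparisons. They were taken among genes with a symbol whose 3 arrays lie on 1 side of the 3 DMSO arrays. In the other comparisons it picked 4 and 4. MET and EGFR were picked too, and up to 4 members of each list that passed camera or had at least 5 members called. So was any MAPK output or aryl hydrocarbon receptor target. The text names only part of the genes picked. Pseudogenes and placeholder identifiers were skipped. Lists were tested with camera (preset correlation 0.01), with an estimated correlation and with fry, adjusted over 24 lists and 8 comparisons (192 tests). Of the 25 lists, the one of fibroblast and mesenchymal markers had 1 tested gene and no test, and leukocyte markers had 3. Tests of lists in doxycycline against PHA-665752, the Fisher tests of lists in the on-target set, list medians under other scalings and the on-target set without doxycycline were added after seeing the data.

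The fit was tested on simulated data made from the real genes, with 200 genes changed. For GTL-16 PHA-665752 against DMSO it recovered 56.7%, 95.5% and 98.5% of genes changed by a log2 of 0.5, 1 and 2, with 4 false calls among 171. For GTL-16 gefitinib it recovered 56.7%, 97% and 100%, with 10 false calls among 179, and for the difference of PHA-665752 effects 19.4%, 82.1% and 100%, with 7 false calls among 141. With the 22 ATF4 genes changed, camera found that list in each of these, and 1, 0 and 0 of the 23 other lists. The simulated genes varied independently, so these false list calls do not carry over to lists whose genes vary together.

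Alternatives were each run on their own: no background correction, normexp by maximum likelihood with an offset of 50 (2 changes at once), cyclic loess or median centring in place of quantile, quantile normalisation and fit within each line (also 2 changes), the authors' processed values, other detection filters, every feature on its own, only the groups compared in the fit, trend and robust moderation, array weights, a replicate block, stricter thresholds, and each array left out in turn. Overlaps were set against 100 simulations of unchanged groups that shared simulated DMSO arrays. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.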

Results

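Transcript levels were measured on 21 Illumina bead arrays, 3 for each of 7 groups. DiFi cells, a colorectal carcinoma line with amplified EGFR, received vehicle (DMSO), the MET kinase inhibitor PHA-665752 or the EGFR kinase inhibitor gefitinib. GTL-16 cells, a gastric carcinoma line with amplified MET that carried a vector for an shRNA against MET in every group, received DMSO, gefitinib, PHA-665752 or doxycycline, which switches that shRNA on. Inhibitors were given at 1 uM for 24 h and doxycycline for 48 h. Between 9263 and 9985 of the 20589 array features were detected per array, and the mean raw signal per array lay between 715 and 1278. Signal over background, the mean raw signal minus the background, was 1005 ± 137 (SD, n = 3) in GTL-16 cells with DMSO, 699 ± 64.1 with PHA-665752, 719 ± 120 with doxycycline and 846 ± 37.2 with gefitinib. In DiFi cells it was 869 ± 140 with DMSO, 869 ± 55.3 with PHA-665752 and 662 ± 20.9 with gefitinib, so the groups in which the amplified receptor was targeted had dimmer arrays. Pairs of arrays from 1 group correlated at a Pearson r of 0.990 to 0.996 across features, which are not independent replicates. The number of arrays, 3 per group, limits the precision.

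MET transcript, the shRNA's target, fell 3.18-fold in GTL-16 cells with doxycycline (log2 change −1.67 ± 0.21 SE, limma adjusted p = 1.76e-06), from a log2 signal of 12.93 ± 0.26 (SD, n = 3) with DMSO to 11.26 ± 0.15. With PHA-665752, which targets the protein, MET was at 12.42 ± 0.37 and did not pass the test against DMSO (adjusted p = 0.0524), and with gefitinib it was at 13.12 ± 0.16 (adjusted p = 0.904). Against gefitinib, MET was 1.63-fold lower with PHA-665752 (−0.71, adjusted p = 0.0109). With DMSO, GTL-16 cells had 6.73-fold more MET transcript than DiFi cells (adjusted p = 3.93e-10), where it was at 10.18 ± 0.44. EGFR, the receptor amplified in DiFi cells, was at 14.33 ± 0.03 there and at 8.67 ± 0.33 in GTL-16 cells, a 50.8-fold difference (adjusted p = 1.92e-18). These EGFR values come from the brightest of 4 features, which fell by 0.40 ± 0.12 (SE) on the log2 scale in DiFi cells with gefitinib (adjusted p = 0.00978). The other 3 EGFR features, detected on 9, 9 and 12 of the 21 arrays, changed there by −0.83 ± 0.11, 0.13 ± 0.12 and −0.37 ± 0.16, so the features do not all give a fall. Between the lines all 4 were higher in DiFi cells, and the size of that difference depended on the feature.

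**Figure D1:**
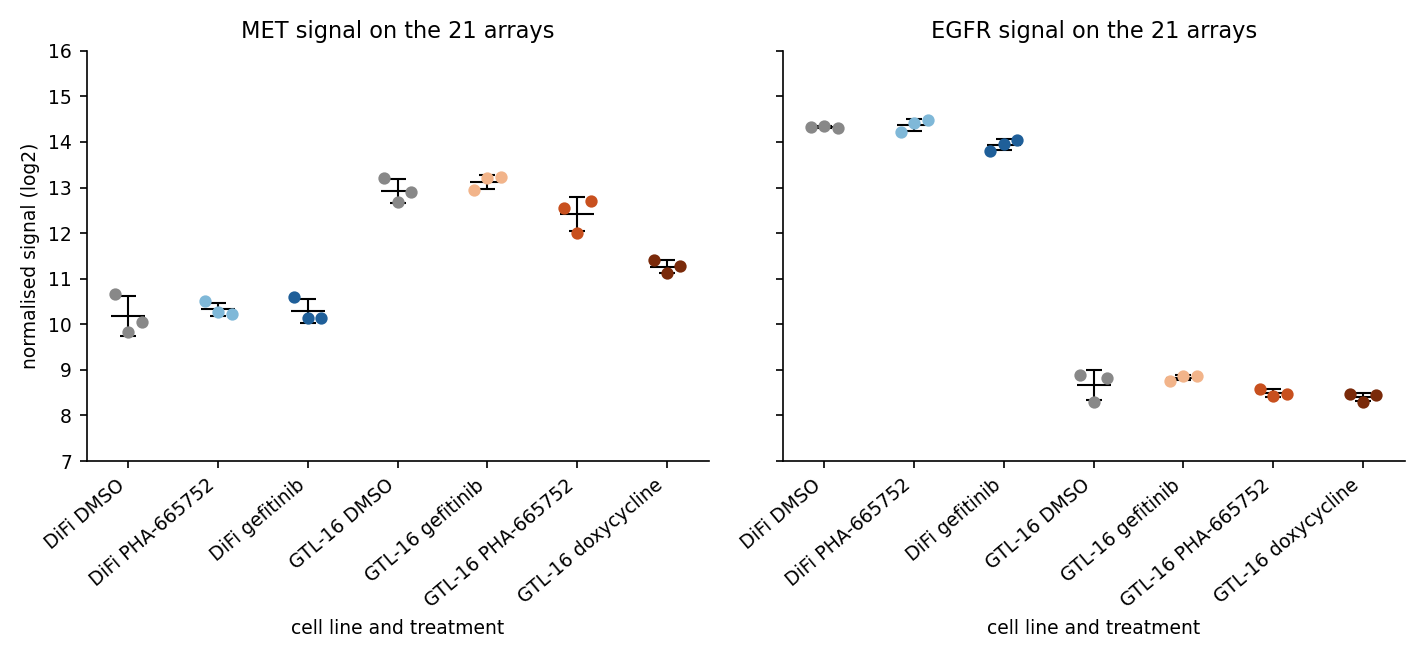
Normalised log2 signal of MET (left) and EGFR (right) on each of the 21 arrays, by cell line and treatment. Points are arrays, horizontal bars are means and error bars are SD (n = 3). MET falls from 12.93 to 11.26 in GTL-16 cells with doxycycline, and EGFR is 50.8-fold higher in DiFi than in GTL-16 cells with DMSO at the feature shown.

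Which transcripts depend on the receptor that is amplified in a line was the question behind the comparisons with DMSO. In each line the inhibitor of the amplified receptor changed a large part of the 11030 tested genes. With the other inhibitor few genes passed the test. PHA-665752 changed 4451 genes in GTL-16 cells (2306 higher, 2145 lower) and 182 in DiFi cells (125 higher, 57 lower). Gefitinib changed 5984 genes in DiFi cells (3270 higher, 2714 lower) and 5 in GTL-16 cells (3 higher, 2 lower). Doxycycline changed 5546 genes in GTL-16 cells (2835 higher, 2711 lower). The 182 calls were not steady: the count was 0 without DiFi DMSO replicate 2 and 1778 with array weights. At an unadjusted limma p under 0.05, PHA-665752 gave 2261 genes in DiFi cells, so 182 calls do not show that few genes changed.

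**Figure D2:**
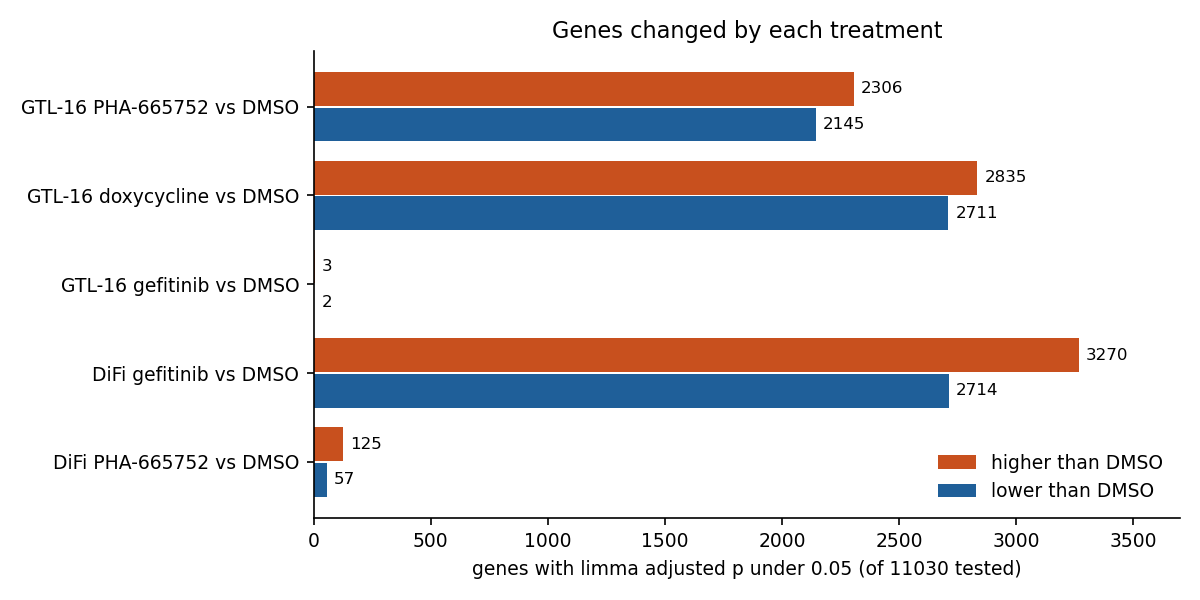
Number of genes with a limma adjusted p under 0.05, of 11030 tested, in each treatment against DMSO of the same line. Orange bars count genes higher than in DMSO and blue bars genes lower, from 5 genes in all for gefitinib in GTL-16 cells to 5984 for gefitinib in DiFi cells.

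In GTL-16 cells with PHA-665752, genes that the MAPK pathway switches on fell together. EGR1, an immediate early transcription factor, fell 11.6-fold (log2 −3.54 ± 0.15 SE, adjusted p = 1.67e-12), MYC 7.83-fold (−2.97 ± 0.12), ETV5 by 3.42 ± 0.12 on the log2 scale, and ETV4 9.39-fold (−3.23 ± 0.12). MYC was detected on 1 of the 3 arrays with PHA-665752, at a mean log2 signal of 6.18, so its fold is not exact. FOS, another immediate early factor, was at least 7.4-fold lower, HBEGF, a ligand of EGFR, at least 5.92-fold lower and IGFBP1, a binding protein of insulin-like growth factors, at least 5.1-fold lower. "At least" marks a gene detected on no array of its dim group. Its fold sets the bright group's mean log2 signal against the mean, over the dim arrays, of the higher of the lowest detected signal and the gene's own signal. Amino acid supply genes fell as well, among them SLC7A5, a transporter of large neutral amino acids (9.29-fold, log2 −3.22 ± 0.08, adjusted p = 5.81e-15), and MTHFD2, a mitochondrial folate enzyme (log2 −2.77). Among the genes that rose most were UGT2B17, a steroid glucuronidation enzyme (6.29-fold, log2 2.65 ± 0.12, adjusted p = 7.67e-12), and PIK3IP1, an inhibitor of PI3 kinase (log2 2.36 ± 0.09, adjusted p = 6.01e-13). TSHZ2 (2.48), COXFA4L3 (2.48), AMOT (at least 3.75-fold) and TM4SF20 (2.32) also rose, and NIBAN1 (−3.52), INHBE (−3.28) and CALB2 (−3.25) fell. UGT2B17 and UGT2B10 (at least 3.84-fold higher) are paralogs, so which member of their family each probe measured is uncertain.

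By gene list, fixed before the data were examined, the fall was broadest in the amino acid response that ATF4 drives: 22 of 22 tested members fell (22 adjusted over the list alone), with a median log2 change of −1.57, or −1.42 with members not detected in a group set at their bound (camera adjusted p = 1.92e-22, and 1.05e-05 with an estimated correlation). STC2 (−3.22 ± 0.13) and TRIB3 (−2.53) were among them. Of 17 MAPK output genes, 15 fell and 1, EPHA4, rose by 0.44 (15 and 1 adjusted over the list alone, median −1.59, or −1.43 at the bounds, camera adjusted p = 2.29e-15, estimated correlation p = 0.000298). DUSP5, a phosphatase that dampens ERK, was at least 5.17-fold lower, and CCND1, which drives entry into the cell cycle, fell by 1.16 on the log2 scale. Ribosome biogenesis genes fell in 24 of 26 cases (24 adjusted over the list alone, median −0.99, camera adjusted p = 2.16e-14, estimated correlation p = 0.000298), with RRP12 and RRP9 both at −1.50. Mitochondrial ribosome genes fell in 11 of 22 cases, with MRPL12 at −0.90 (13 adjusted over the list alone, median −0.26, camera adjusted p = 0.000515, estimated correlation p = 0.0276). Of 15 endoplasmic reticulum chaperone genes 8 fell (9 adjusted over the list alone, median −0.34, or −0.25 at the bounds, camera adjusted p = 0.000169, estimated correlation p = 0.0334), led by HSPA5, the main chaperone of that compartment (−1.51 ± 0.08). Genes that PI3 kinase holds down through FOXO factors went the other way: 14 of 21 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.75, camera adjusted p = 1.11e-06, estimated correlation p = 0.00944), including TNFSF10, a death ligand (2.07), KLHL24 (1.71) and FOXO4 (1.70).

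Cell cycle genes split by phase under PHA-665752. Of 35 genes of G1/S and DNA replication 27 fell (30 adjusted over the list alone, median −0.71, or −0.69 at the bounds), for example MCM10 (−1.83) and E2F2 (−1.47), with a camera adjusted p = 5.49e-11, and adjusted p = 0.071 with an estimated correlation. Of 32 genes of G2/M and mitosis 25 rose and 0 fell (28 and 0 adjusted over the list alone, median 0.62), for example KIF20A, a mitotic kinesin (3.09-fold, 1.63 ± 0.13, adjusted p = 1.37e-08), DLGAP5 (1.49) and ASPM (1.28). That list's camera adjusted p was 3.64e-09, and adjusted p = 0.202 with an estimated correlation. Secreted growth factor, cytokine and protease genes fell in 7 and rose in 2 of 13 cases (7 and 2 adjusted over the list alone, median −0.52, or −0.11 at the bounds, camera adjusted p = 0.0493, and adjusted p = 0.0953 with an estimated correlation), with PLAUR 2-fold lower and PLAU at 0.98.

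In GTL-16 cells with doxycycline, the same kinds of genes moved. SLC7A5 fell 14.9-fold (log2 −3.90 ± 0.08, adjusted p = 1.8e-16), NIBAN1 was at least 16.4-fold lower (−4.76 ± 0.11, adjusted p = 7.39e-16), and EGR1 (−3.13), MYC (−2.61), ETV5 (−2.59) and ETV4 (−2.37) fell. INHBE (−3.64), CALB2 (−3.52) and DTL, which helps to degrade replication licensing factors (−3.44), fell too, and IGFBP1 was at least 5.15-fold lower. Large rises were seen in COXFA4L3 (8.98-fold, 3.17 ± 0.08, adjusted p = 2.17e-15), SLC6A16 (at least 6.24-fold), CFB, a complement factor (3.03), and TSHZ2 (2.99). GSTA5 (2.94) and GSTA2 (2.82), near-identical glutathione transferases, rose as well, with the same doubt about which one a probe measured.

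The ATF4 list fell in 22 of 22 genes with doxycycline (22 adjusted over the list alone, median −1.67, or −1.63 at the bounds, camera adjusted p = 1.37e-17, estimated correlation p = 1.99e-05). MAPK output genes fell in 15 of 17 cases (15 adjusted over the list alone, median −1.51, or −1.28 at the bounds, camera adjusted p = 3.03e-10, estimated correlation p = 0.00146). Chaperone genes of the endoplasmic reticulum fell in 14 of 15 cases (14 adjusted over the list alone, median −0.74, or −0.52 at the bounds, camera adjusted p = 3.58e-06, estimated correlation p = 0.0127), with HSPA5 3.34-fold lower (−1.74 ± 0.08). Ribosome biogenesis genes fell in 23 of 26 cases (24 adjusted over the list alone, median −1.07, camera adjusted p = 1.8e-12, estimated correlation p = 0.000534) and mitochondrial ribosome genes in 17 of 22 (17 adjusted over the list alone, median −0.38, camera adjusted p = 6.11e-05, estimated correlation p = 0.0127). FOXO and PI3K-restrained genes rose in 14 of 21 cases and fell in 1 (15 and 1 adjusted over the list alone, median 0.75, camera adjusted p = 4.48e-07, estimated correlation p = 0.0077), with PIK3IP1 at 2.74 and TNFSF10 at 2.33. Both cell cycle lists fell: 33 of 35 G1/S genes (34 adjusted over the list alone, median −1.18, or −1.16 at the bounds, camera adjusted p = 5.36e-16, estimated correlation p = 0.0276) and 32 of 32 G2/M genes (32 adjusted over the list alone, median −1.17, or −1.11 at the bounds). KIF2C, a mitotic kinesin, fell 4.7-fold (−2.23 ± 0.15, adjusted p = 4.68e-10). The G2/M list had a camera adjusted p = 2.43e-15, and adjusted p = 0.0731 with an estimated correlation. Doxycycline arrays came from 48 h and DMSO arrays from 24 h, and no cells without the shRNA received doxycycline, so time, doxycycline and loss of MET are not separated.

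Changes under PHA-665752 and doxycycline ran together across genes, which are not independent replicates (Pearson r = 0.875, Spearman rho = 0.857, covariance 0.274). Both treatments raised 1966 genes and lowered 1862, where independent lists of these sizes would share 593 and 527, and 64 genes were called in opposite directions (1118 for independent lists). Unchanged groups simulated against 3 shared, also simulated, DMSO arrays gave r = 0.5, a covariance of 0.0103 and 0 shared calls. With no gene changed few calls could arise, so that 0 does not gauge the excess over independent lists. Part of the excess may come from the shared DMSO arrays, which are too few to divide.

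Compared directly, doxycycline and PHA-665752 differed in 1187 genes (537 higher, 650 lower with doxycycline), and the 123 genes at least 2-fold lower outnumbered the 17 at least 2-fold higher. CDCA3, which triggers entry into mitosis, was 7.51-fold lower with doxycycline (−2.91 ± 0.18, adjusted p = 1.93e-09), as were the mitotic kinase TTK (−2.66), the centromeric histone CENPA (−2.64 ± 0.15) and PLK1 (at least 3.25-fold). All 32 G2/M genes were lower (32 adjusted over the list alone, median −1.98, or −1.94 at the bounds, camera adjusted p = 6.26e-74, estimated correlation p = 0.000722). In G1/S 19 of 35 genes were lower (22 adjusted over the list alone, median −0.45, or −0.39 at the bounds, camera adjusted p = 1.61e-16, estimated correlation p = 0.0295), for example TK1 (−1.45). Of 15 chaperone genes 2 were lower (8 adjusted over the list alone, median −0.25, camera adjusted p = 6.5e-05, estimated correlation p = 0.0295), DNAJB11 among them (2-fold). MAPK output genes were higher in 3 cases, ETV4 (0.86) and ETV5 (0.82) among them, and lower in 2, EMP1 and EPHA4 (both −0.51), of 17 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00233, and adjusted p = 0.0728 with an estimated correlation). CRIP2 (1.62 ± 0.17), GADD45G (1.58) and SLC6A16 (1.47) were higher with doxycycline, and MET itself was 2.22-fold lower (−1.15 ± 0.21, adjusted p = 0.000876).

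**Figure D3:**
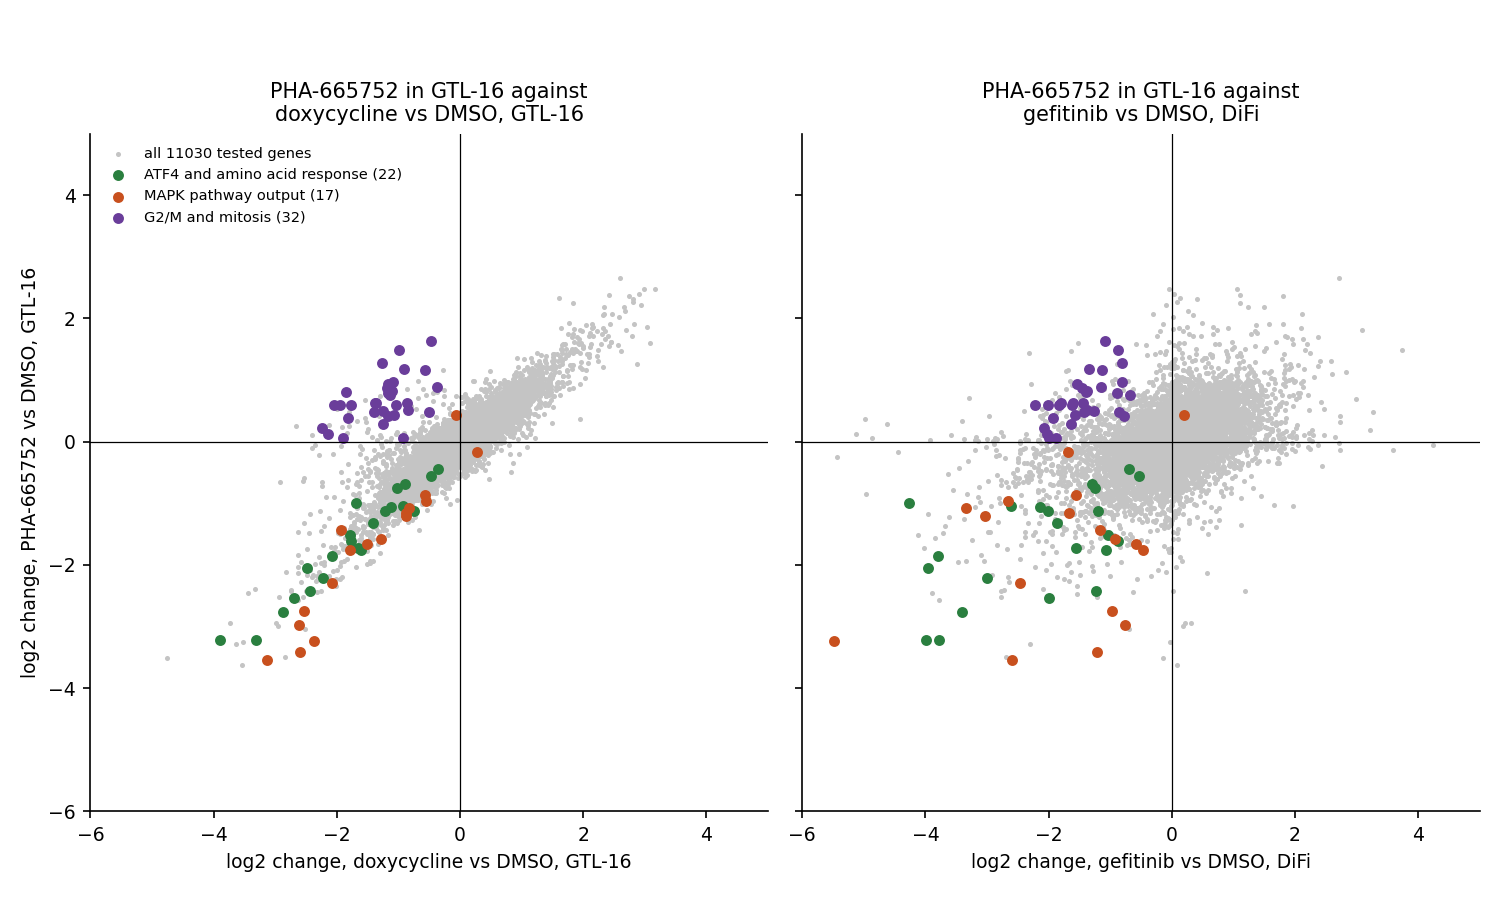
Log2 change of each of the 11030 tested genes with PHA-665752 in GTL-16 cells (vertical axis) against the change with doxycycline in GTL-16 cells (left) or with gefitinib in DiFi cells (right). Grey points are all genes, green the 22 ATF4 genes, orange the 17 MAPK output genes and purple the 32 G2/M genes, which lie above 0 on the vertical axis and below 0 on both horizontal axes. Values of genes not detected in a group are fitted values.

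Gefitinib in GTL-16 cells, the control inhibitor there, passed the test for 5 genes. UGT2B17 (0.74, adjusted p = 0.0348), TMEM139 (0.52, adjusted p = 0.0312) and PIK3IP1 (0.51, adjusted p = 0.048) rose, and ATP8B1 (−0.67, adjusted p = 0.0312) and EIF2S2 (−0.58, adjusted p = 0.0413) fell. All 5 changed in the same direction with PHA-665752, which was compared with the same DMSO arrays. At an unadjusted limma p under 0.05 there were 794 genes, and 0 of the 5 changed 2-fold. None of 17 MAPK output genes passed the test, over all genes or adjusted over the list alone. G1/S genes had a median of −0.15 (0 of 35 past the test, camera adjusted p = 1.01e-07, and adjusted p = 0.139 with an estimated correlation). G2/M genes had a median of −0.12 (camera adjusted p = 0.000344, and adjusted p = 0.477 with an estimated correlation). FOXO and PI3K-restrained genes had a median of 0.11, or 0.09 at the bounds, with 1 of 21 past the test and 3 adjusted over the list alone (camera adjusted p = 0.00173, and adjusted p = 0.071 with an estimated correlation). ATF4 genes (median −0.05), ribosome biogenesis genes (−0.07), mitochondrial ribosome genes (−0.06) and cholesterol synthesis genes (−0.13) had camera adjusted p = 0.0132, 0.0194, 0.0294 and 0.0191, and adjusted p = 0.0686, 0.14, 0.139 and 0.307 with an estimated correlation. The count of 5 rested on single arrays and settings: it was 0 without DMSO replicate 3 or gefitinib replicate 2, 1 without DMSO replicate 2 or gefitinib replicate 1, and 3 without gefitinib replicate 3.

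In DiFi cells with gefitinib, the drops were the deepest of the series. CEACAM6, a cell surface adhesion molecule of gut epithelium, fell 43.2-fold (−5.43 ± 0.11, adjusted p = 2.34e-17), ETV4 was at least 21.3-fold lower (−5.49 ± 0.12, adjusted p = 7.6e-17), and REG1A, a secreted regenerating protein with close paralogs, was 35-fold lower (−5.13 ± 0.15). PAPSS2, a sulfate donor synthase (at least 14.5-fold), GRM8 (at least 13.1-fold), CDCA7 (−4.97) and COL5A1 (−4.62) fell as well. Serine and amino acid genes fell steeply: PHGDH, the first enzyme of serine synthesis, 19.2-fold (−4.26 ± 0.12, adjusted p = 1.39e-15), ASNS, asparagine synthetase, 15.5-fold (−3.95 ± 0.11), and SLC7A5 15.9-fold (−3.99 ± 0.08, adjusted p = 3.04e-17). BMP6, a signalling ligand, rose 18.9-fold (4.24 ± 0.12, adjusted p = 1.68e-15), and TP53INP2, an autophagy factor (3.73 ± 0.13), PGM1, a glycogen enzyme (9.33-fold, 3.22 ± 0.08), TP53INP1 (3.09) and SH3GL2 (at least 5.12-fold) rose.

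All 22 ATF4 genes fell in DiFi cells with gefitinib (22 adjusted over the list alone, median −1.93, or −1.70 at the bounds, camera adjusted p = 7.26e-18, estimated correlation p = 1.99e-05). MAPK output genes fell in 16 of 17 cases (16 adjusted over the list alone, median −1.56, camera adjusted p = 1.17e-10, estimated correlation p = 0.00127), with SPRED1, an inhibitor of RAS signalling, at −3.35, EPHA2 at −3.03 and MYC at −0.76. In G1/S 34 of 35 genes fell (34 adjusted over the list alone, median −2.58, or −2.39 at the bounds, camera adjusted p = 4.77e-25, estimated correlation p = 0.00733). CDC45 (at least 11-fold) and E2F1 (at least 9.74-fold) were among them. All 32 G2/M genes fell (32 adjusted over the list alone, median −1.43, or −1.40 at the bounds, camera adjusted p = 4.68e-16, and adjusted p = 0.071 with an estimated correlation), with CCNA2 at −2.22 ± 0.10. Ribosome biogenesis genes fell in 23 of 26 cases (23 adjusted over the list alone, median −0.91, camera adjusted p = 9.1e-11, estimated correlation p = 0.00104) and mitochondrial ribosome genes in 16 of 22 (16 adjusted over the list alone, median −0.45, camera adjusted p = 5.7e-05, estimated correlation p = 0.0127). FOXO and PI3K-restrained genes rose in 15 and fell in 3 of 21 cases (15 and 3 adjusted over the list alone, median 1.12, or 0.85 at the bounds, camera adjusted p = 0.000362, estimated correlation p = 0.0431), with BCL6 (2.60) and FOXO4 (2.38) higher and IRS2 (−2.47) lower. HSPA5 rose by 0.59 ± 0.08 (adjusted p = 4.09e-06). Of its 15 chaperone genes 7 rose and 1, XBP1, fell by 0.38 (7 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.43).

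In DiFi cells with gefitinib, immediate early genes fell in 6 and rose in 2 of 9 cases (6 and 2 adjusted over the list alone, median −0.54, camera adjusted p = 0.0308, and adjusted p = 0.167 with an estimated correlation). FOS was at least 3.08-fold and EGR1 at least 3.38-fold lower, and JUN was 0.81 higher. Growth factor, cytokine and protease genes fell in 7 and rose in 1 of 13 cases (7 and 1 adjusted over the list alone, median −0.47, or 0 at the bounds, camera adjusted p = 0.0227, and adjusted p = 0.0681 with an estimated correlation), with PLAUR at −1.74 and GDF15 at −1.32. Glycolysis and hypoxia genes fell in 15 and rose in 3 of 21 cases (15 and 3 adjusted over the list alone, median −0.42, or −0.37 at the bounds, camera adjusted p = 0.0041, and adjusted p = 0.128 with an estimated correlation). HK2, which starts glycolysis, fell 3.49-fold (−1.80 ± 0.11), and NDRG1 (1.79) and ADM (1.69) rose. The counts of falls with gefitinib include genes detected in neither group: DUSP6 of MAPK output, HBEGF and VEGFA of the growth factor list and ENO2 and VEGFA of the glycolysis list. So do those of G1/S in GTL-16 cells, with CDC6 under PHA-665752 and doxycycline.

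**Figure D4:**
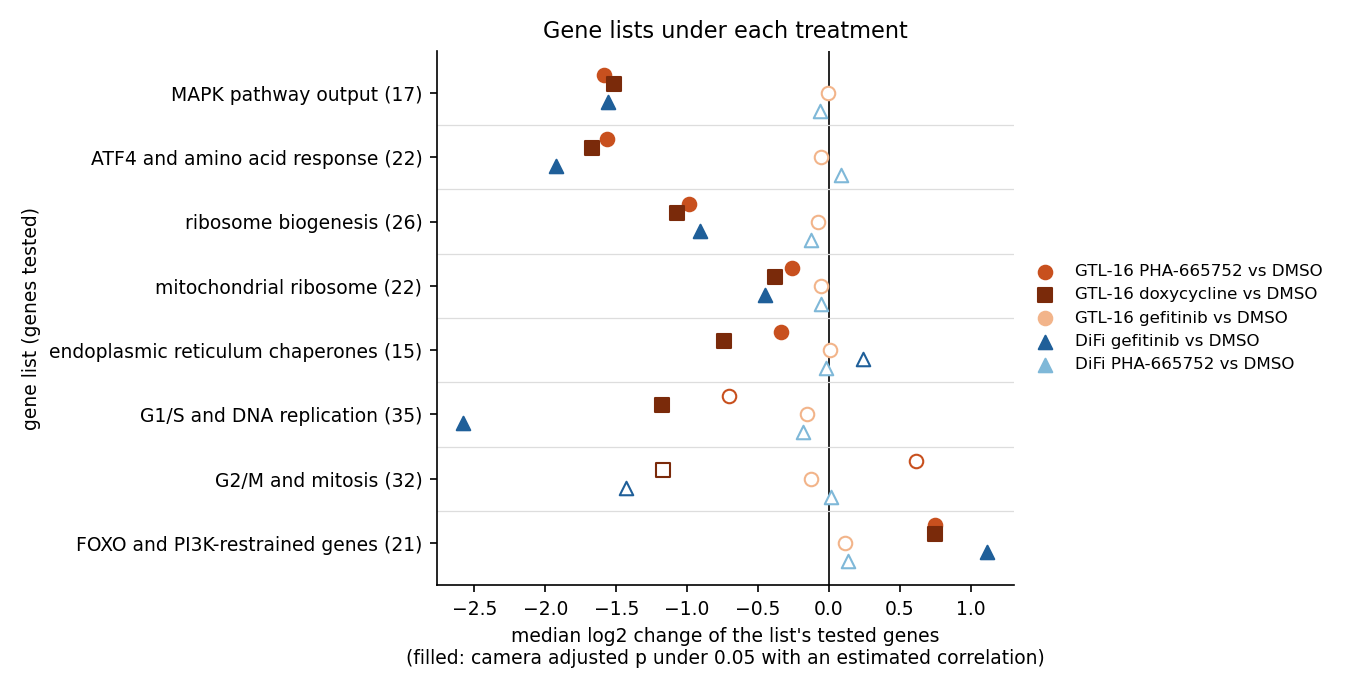
Median log2 change against DMSO of the tested genes of 8 gene lists (number tested in brackets) in the 5 treatments. Filled symbols have a camera adjusted p under 0.05 with an estimated correlation, open symbols do not. The control inhibitors lie near 0 throughout, and G2/M genes lie at 0.62 with PHA-665752 in GTL-16 cells, at −1.17 with doxycycline and at −1.43 with gefitinib in DiFi cells.

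PHA-665752 in DiFi cells, the control inhibitor there, changed 182 genes, 2 of them 2-fold. IGIP was higher by 1.07 ± 0.24 (adjusted p = 0.0324), as were CCDC121 (0.87), ZNF518A (0.78) and BTC, a ligand of EGFR (at least 1.22-fold, 0.74 ± 0.11, adjusted p = 0.00699). OGFOD3 (at least 1.37-fold, −0.82, adjusted p = 0.00398), AKR1B10, an aldo-keto reductase (−0.74, adjusted p = 0.0161), TNFAIP8L1 (−0.72) and BCL9L (−0.69) were lower. Of 18 cholesterol synthesis genes EBP (−0.39) and TMEM97 (−0.32) fell (4 lower and 1 higher adjusted over the list alone, median −0.21, camera adjusted p = 0.011, and adjusted p = 0.268 with an estimated correlation). Glycolysis and hypoxia genes had a median of −0.16, or −0.14 at the bounds (0 of 21 past the test, 4 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000525, and adjusted p = 0.071 with an estimated correlation). G1/S genes had a median of −0.18 (0 of 35 past the test, 2 lower adjusted over the list alone, camera adjusted p = 0.000247, and adjusted p = 0.316 with an estimated correlation). None of the 17 MAPK output genes passed. The count depended on every array: it was 22, 0 and 66 without DMSO replicates 1, 2 and 3, and 405, 7 and 6 without PHA-665752 replicates 1, 2 and 3.

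The difference between lines was itself tested. The effect of PHA-665752 differed between GTL-16 and DiFi cells for 2931 genes, and that of gefitinib for 4337. For PHA-665752 the ATF4 list stood lowest in GTL-16 relative to DiFi (21 of 22 genes lower, 22 adjusted over the list alone, median −1.79, camera adjusted p = 2.24e-25, estimated correlation p = 9e-06), then MAPK output (15 of 17 lower and 1 higher, 15 and 1 adjusted over the list alone, median −1.53, camera adjusted p = 5.36e-16, estimated correlation p = 0.000297). EGR1 (−3.57) and ETV5 (−3.54) were lower in that difference as well. For gefitinib, G1/S genes stood lowest in DiFi relative to GTL-16 (34 of 35 lower, 34 adjusted over the list alone, median −2.23, camera adjusted p = 8.72e-28, estimated correlation p = 0.00475), then the ATF4 list (20 of 22 lower, 22 adjusted over the list alone, median −1.83, camera adjusted p = 3.19e-20, estimated correlation p = 1.36e-05). CEACAM6 (−5.35) and PHGDH (−4.18) were lower in that difference, and TP53INP2 (3.60) and PGM1 (3.19) higher.

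**Figure D5:**
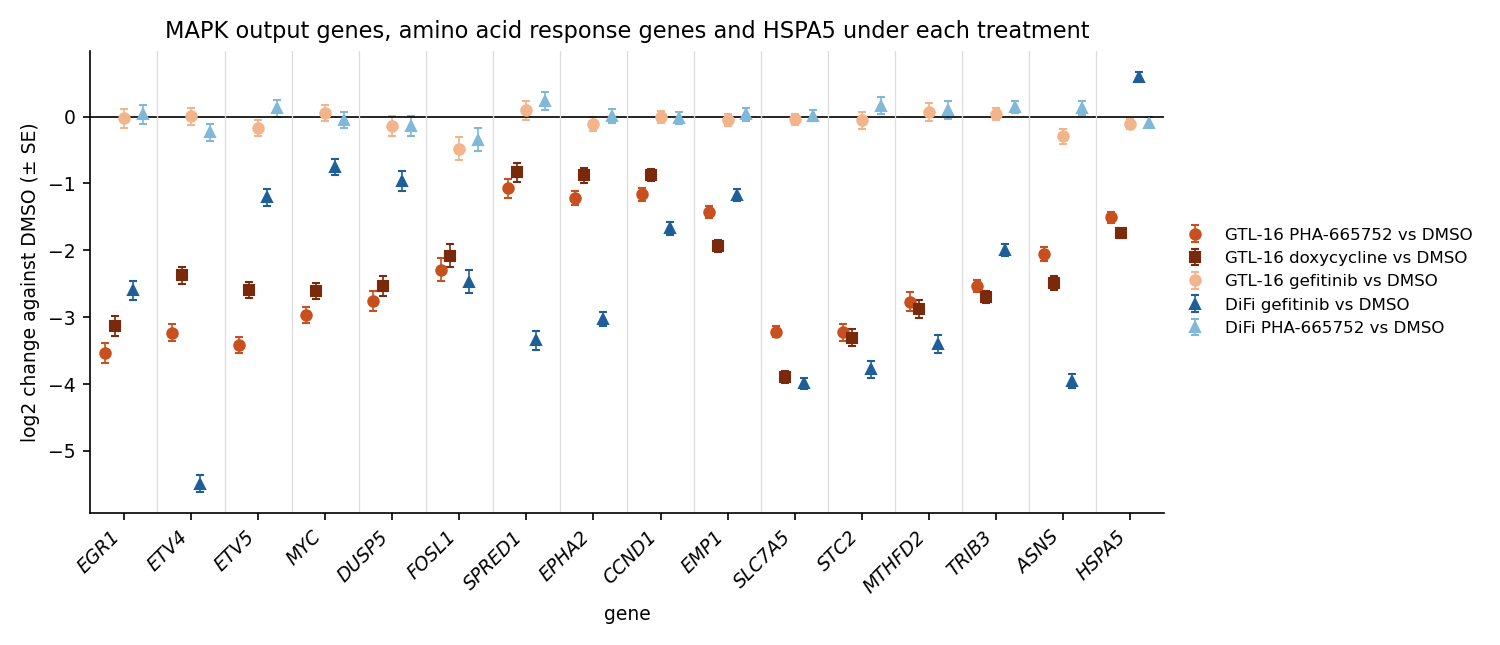
Log2 change against DMSO (points, with SE as error bars) of 10 MAPK output genes, 5 amino acid response genes and HSPA5 in the 5 treatments. The control inhibitors lie near 0 and the inhibitor of the amplified receptor lowers each gene shown, except HSPA5, which falls in GTL-16 cells and rises by 0.59 in DiFi cells with gefitinib. Of all 17 tested MAPK output genes, 15 fell and 1, EPHA4, rose with PHA-665752 in GTL-16 cells. Values of genes not detected in a group are fitted values.

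Changes shared by the on-target treatments, PHA-665752 and doxycycline in GTL-16 and gefitinib in DiFi cells, were counted next. PHA-665752 in GTL-16 and gefitinib in DiFi cells raised 1383 genes and lowered 1219 in common (684 and 528 for independent lists), and 409 went opposite ways. Their changes correlated across genes with r = 0.472 and rho = 0.482. All 3 treatments changed 2381 genes the same way. Independent lists would give 305, but PHA-665752 and doxycycline share DMSO arrays and 3828 calls, so 305 is too low a baseline. Of the 2381 genes, 1808 also differed from the control inhibitor of their line, 928 higher and 880 lower. Among these, 229 changed 2-fold in each treatment, 76 up and 153 down. SLC7A5 (mean −3.70) and DTL (−3.26) were among the genes that fell, and UGT2B17 (2.65), PIK3IP1 (2.30), TP53INP2 (2.29), TP53INP1 (2.28) and COXFA4L3 (2.23) among those that rose. With gefitinib in GTL-16 cells UGT2B17 (0.74) and PIK3IP1 (0.51) rose past the test as well. COXFA4L3 (0.41), TP53INP1 (0.29) and TP53INP2 (0.13) were higher there without passing it. The 880 lower genes held 22 of 22 ATF4 genes (one-sided Fisher's exact test, adjusted p = 2.61e-23), 23 of 35 G1/S genes (3.35e-16), 18 of 26 ribosome biogenesis genes (1.48e-13) and 15 of 17 MAPK output genes (5.65e-14). DUSP6, among these 15, was detected in DiFi cells neither with gefitinib nor with DMSO. The 928 higher genes held 12 of 21 FOXO and PI3K-restrained genes (1.62e-07) and 5 of 15 p53 targets (0.049), while the p53 targets AEN and TNFRSF10B were among the lower genes. Fisher's test takes genes as independent, so these p-values may be too small where members vary together. SESN1 counts in both lists, and p53 targets did not pass camera with PHA-665752, doxycycline or gefitinib in DiFi (adjusted p = 0.546, 0.439 and 0.616). No G2/M or chaperone gene was in the set. Under the control inhibitor, the 928 higher genes had a median of 0.07 in GTL-16 and 0.01 in DiFi cells, and the 880 lower genes −0.05 and −0.08.

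The on-target effects also differed between lines, for 3684 genes (1784 higher and 1900 lower in GTL-16 with PHA-665752 than in DiFi with gefitinib). All 32 G2/M genes were higher in that difference (32 adjusted over the list alone, median 2.17, camera adjusted p = 1.14e-28, estimated correlation p = 0.0152), KIF20A by 2.72 and CCNA2 by 2.82. So were 33 of 35 G1/S genes (33 adjusted over the list alone, median 1.75, camera adjusted p = 3.28e-24, estimated correlation p = 0.0077), CDT1 by 3.16. Of 22 ATF4 genes 13 were higher and 4 lower (13 and 4 adjusted over the list alone, median 0.55, camera adjusted p = 0.0015, estimated correlation p = 0.0267), with PHGDH at 3.27. Chaperone genes were lower in 10 of 15 cases and higher in 1 (11 and 1 adjusted over the list alone, median −0.52, camera adjusted p = 0.000148, estimated correlation p = 0.0326), with HSPA5 at −2.10 ± 0.11. MYC (−2.21) was lower in that difference and CEACAM6 (5.18) higher. Of the 192 camera tests over 24 lists and 8 comparisons, 63 passed and 34 of those passed with an estimated correlation. The lists in doxycycline against PHA-665752 were tested outside these 192.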

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

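Of the tests in this part, those of the GTL-16 DMSO arrays, of longer treatment or doxycycline itself and of list medians under other scalings were chosen only after the data were seen. The results listed first differ between the 2 cell lines by a test of the difference itself.

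PHA-665752 acted differently in GTL-16 and DiFi cells on 2931 genes. The difference, GTL-16 minus DiFi on the log2 scale, was fitted as 2.48 for FXYD2, 2.47 for COXFA4L3, 2.46 for UGT2B17, 2.44 for TM4SF20, −3.60 for IGFBP1, −3.57 for EGR1, −3.54 for ETV5 and −3.54 for HBEGF. FXYD2, TM4SF20, IGFBP1 and HBEGF were undetected in at least 1 of the 4 groups, so their sizes are not exact and they are not ranked. List medians of that difference were −1.79 for the ATF4 response, −1.53 for MAPK output, −0.87 for ribosome biogenesis (estimated correlation p = 0.000453), 0.59 for FOXO and PI3K-restrained genes (0.0127) and −0.41 for endoplasmic reticulum chaperones (0.0496). Medians of −0.57 for G1/S, 0.60 for G2/M, −0.55 for growth factors, cytokines and proteases and −0.23 for the mitochondrial ribosome passed camera, with adjusted p = 0.18, 0.246, 0.071 and 0.071 with an estimated correlation. Of the 200 splits of these arrays 5 gave as many genes, the real one included (highest other 3616). All 5 kept the GTL-16 arrays in their real groups and with them that line's effect, so this count does not decide whether chance is excluded.

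Gefitinib acted differently in DiFi and GTL-16 cells on 4337 genes. The difference, DiFi minus GTL-16, was fitted as 3.91 for BMP6, 3.71 for SH3GL2, 3.60 for TP53INP2, 3.19 for PGM1, −5.49 for ETV4, −5.35 for CEACAM6, −5.08 for PAPSS2 and −5.01 for REG1A. BMP6, SH3GL2, ETV4, PAPSS2 and REG1A were undetected in at least 1 of the 4 groups, with the same limit. List medians were −2.23 for G1/S, −1.83 for the ATF4 response, −1.66 for MAPK output (estimated correlation p = 0.00104), −0.85 for ribosome biogenesis (0.00127), −0.40 for the mitochondrial ribosome (0.0326) and 0.76 for FOXO and PI3K-restrained genes (0.0496). Medians of −1.35 for G2/M, −0.45 for immediate early genes, −0.24 for growth factors, cytokines and proteases, −0.43 for glycolysis and hypoxia and 0.29 for lysosome and autophagy passed camera, with adjusted p = 0.071, 0.125, 0.071, 0.176 and 0.175 with an estimated correlation. Here 19 of 200 splits gave as many genes (highest other 4934). All 19 kept the DiFi arrays in their real groups, with the same limit.

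On-target effects, PHA-665752 in GTL-16 minus gefitinib in DiFi cells, differed for 3684 genes. Fitted differences were 5.35 for PAPSS2, 5.25 for REG1A, 5.18 for CEACAM6, 4.93 for GRM8, −4.29 for BMP6, −3.72 for SH3GL2, −3.71 for IGFBP1 and −3.61 for KANK4. Of these only CEACAM6 was detected in all 4 groups, so the other sizes are not exact and not ranked. List medians were 2.17 for G2/M, 1.75 for G1/S, 0.55 for the ATF4 response, −0.52 for endoplasmic reticulum chaperones and 0.16 for receptor tyrosine kinases and feedback adaptors, the last with adjusted p = 0.0729 with an estimated correlation. As many genes came from 11 of 200 splits (highest other 6541), and all 11 kept the DiFi arrays in their real groups, so whether chance is excluded is left undecided here too.

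G2/M genes were higher in GTL-16 cells with PHA-665752 (median 0.62) and lower with doxycycline (median −1.17). For the rise with PHA-665752, the values argue against scaling and background correction as the source: the lowest median over the other settings was 0.54. They argue against any 1 array as well, since the lowest median without an array was 0.56, without GTL-16 DMSO replicate 1. The DMSO arrays are excluded as the source of that rise, since PHA-665752 against gefitinib, which uses none, gave a median of 0.80. These values do not cover the fall with doxycycline. The longer treatment or doxycycline itself cannot be told apart from the loss of MET, since the direct comparison (median −1.98) has no treatment time in common. The list's calls against DMSO are lost with an estimated correlation.

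Chaperone genes of the endoplasmic reticulum were lower in GTL-16 cells with PHA-665752 than in DiFi cells with gefitinib. The median difference of −0.52 was at most −0.46 over the other scalings and background corrections, which excludes these as the source. Random lists matched on the DMSO difference and on mean level argue against an unequal starting level in the lines. Of 10000 such lists 0.06% had a median as low, the real list counted in. Their genes were drawn independently, so that share may be too low for genes that vary together. Signal over background, 699 and 662 in these groups, was not tested as a cause and stays open beside a difference between the lines, which the design holds together with the inhibitor.

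The other results across all genes were set against other splits of their arrays. For each comparison of 3 arrays with 3, the 10 splits are too few for a share under 0.05, and the 1 split as large was the real one. The highest other split gave 1 gene for PHA-665752 in GTL-16 (real 4451), 1 for doxycycline (5546), 0 for gefitinib in GTL-16 (5), 1 for gefitinib in DiFi (5984), 2 for PHA-665752 in DiFi (182), 2 for doxycycline against PHA-665752 (1187) and 0 for the lines with DMSO (8422). For the 3828 genes that PHA-665752 and doxycycline shared, the highest other split gave 29 (1 of 100 splits as large). For the 2602 that PHA-665752 in GTL-16 and gefitinib in DiFi cells shared, it gave 409 (1 of 200). For the on-target set of 1808 it gave 0. Splits that mix treated and DMSO arrays call few genes (median of the others 0 for all 3). The real groups gave more genes than any other split drawn for all 3. Since mixed splits call few genes in any case, these counts do not decide whether chance is excluded. They also do not test whether the lists overlap more than unrelated lists would. Chance is not excluded for the 63 gene list calls by camera with a preset correlation, which 6 of 100 splits matched (highest other 71, median of the others 45). For the 34 calls with an estimated correlation the other splits gave 0. In splits that mix treated and DMSO arrays, treatment effects stay in the spread from which that correlation is estimated. That 0 therefore does not decide whether chance is excluded.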

How the results depend on the processing

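Of the tests in this part, only the on-target set without doxycycline was chosen after seeing the data. Counts for PHA-665752 and doxycycline in GTL-16 and gefitinib in DiFi cells stayed within 1.5 times their value under every scaling, background correction, filter and fit tried, and moved only when a 2-fold change was required: to 561, 1049 and 1316. That requirement also gave 597, 1257 and 1090 for the differences of PHA-665752, gefitinib and on-target effects, 498 and 245 for the genes PHA-665752 shared with doxycycline and with gefitinib in DiFi cells, 158 for the on-target set, 140 for doxycycline against PHA-665752 and 3894 for the lines with DMSO. An adjusted p under 0.01 gave 616 for doxycycline against PHA-665752 and 1745 for the PHA-665752 difference. With only the compared groups in the fit doxycycline against PHA-665752 gave 589, with fewer arrays to estimate the spread. Features detected on all 21 arrays gave 5517 between the lines, with fewer genes tested. Camera passed 63 list tests, 34 with an estimated correlation, and fry, which asks only whether a list moves, 118. The on-target set held 2381 genes without the conditions against the control inhibitors and 1917 without doxycycline.

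Control inhibitors gave the counts that moved most, and the cause was not tested. For gefitinib in GTL-16 cells (5) the count was 2 without background correction, 2 with maximum likelihood normexp and an offset of 50, 9 with median centring, 11 with array weights, and 0 with quantile normalisation and fit within each line, without a detection filter, with only the compared groups in the fit, at 2-fold and at an adjusted p under 0.01. For PHA-665752 in DiFi cells (182) it was 443 without background correction, 450 with the authors' values, 35 with normalisation and fit within each line, 54 without a detection filter, 431 for features detected on all arrays, 0 with only the compared groups, 512 with trend and robust moderation, 1778 with array weights, 2 at 2-fold and 5 at an adjusted p under 0.01.

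Leaving out each array gave 3906 to 4153 genes for PHA-665752 and 5074 to 5206 for doxycycline in GTL-16, 5451 to 5590 for gefitinib in DiFi, 862 to 1083 for doxycycline against PHA-665752, 2491 to 2861, 3954 to 4245 and 3285 to 3636 for the PHA-665752, gefitinib and on-target differences, 8096 to 8236 for the lines, 3398 to 3671 and 2346 to 2516 for the shared genes, 1623 to 1812 for the on-target set and 60 to 65 list calls. For gefitinib in GTL-16 the range was 0 to 5: 0 without DMSO replicate 3 or gefitinib replicate 2, 1 without DMSO replicate 2 or gefitinib replicate 1, 3 without gefitinib replicate 3. For PHA-665752 in DiFi it was 0 to 405: 22, 0 and 66 without DMSO replicates 1, 2 and 3, and 405, 7 and 6 without PHA-665752 replicates 1, 2 and 3.

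A replicate block was fitted as an alternative, since whether replicate numbers pair the arrays is not settled. Over 27 same-numbered pairs of groups the correlation of deviations ran from −0.147 to 0.374, and 14 were above 0.1. GTL-16 DMSO with doxycycline gave 0.204, 0.199 and 0.118, and GTL-16 DMSO with gefitinib −0.147, −0.031 and 0.021. In every other group of their line, 6 of 21 arrays correlated best with their own number, so pairing of some groups is possible. The main fit has no block. With the block, gefitinib in GTL-16 gave 0 genes and no other count moved by over 1.5 times (4692 for PHA-665752, 5727 for doxycycline, 6161 for gefitinib in DiFi, 140 for PHA-665752 in DiFi). A slide block was not run, since the sources used here name no slides.

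With median centring in place of quantile the median of all genes was 0.12 for PHA-665752 and 0.16 for doxycycline in GTL-16, 0.16 for gefitinib in DiFi, 0.12 for the PHA-665752 difference and 0.11 for the gefitinib difference. With the authors' values it was 0.15 for doxycycline, 0.11 for gefitinib in DiFi and −0.31 between the lines. With quantile it lay between −0.04 and 0.05 for every comparison. Median centring gave 3045 higher and 1872 lower (61.9% higher, 51.8% in the report) for PHA-665752, 3962 and 2339 (62.9%, 51.1%) for doxycycline, 7 and 2 (77.8%, 60%) for gefitinib in GTL-16, 101 and 84 (54.6%, 68.7%) for PHA-665752 in DiFi and 2050 and 1157 (63.9%, 51.7%) for the PHA-665752 difference. The authors' values gave 3275 and 2035 (61.7%) for doxycycline, 5 and 2 (71.4%) for gefitinib in GTL-16, 396 and 54 (88%) for PHA-665752 in DiFi and 3102 and 5303 (36.9%, 49.1%) between the lines, and normalisation and fit within each line 17 and 18 (48.6%) for PHA-665752 in DiFi.

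Of 680 values past the threshold among genes picked for naming, 416 stayed past it under all settings. Values not tested under a setting count as staying. The 2-fold requirement lost 246 and an adjusted p under 0.01 lost 61. Scalings, background corrections and fits lost from 2 (trend and robust moderation) to 56 (the authors' values). With the authors' values 5 reversed: ETV5 (2.68, from −2.21), EGR1 (0.22, from −0.94), FOS (1.61, from −0.80) and HBEGF (0.48, from −2.36) in the on-target difference, and CYP1B1 (−2.54, from 0.21) in the PHA-665752 difference, all undetected in at least 1 group compared. With median centring CYP1A1 in GTL-16 with doxycycline reversed (0.51, from −0.01). The cause was not tested. Signal over background (699 with PHA-665752 and 1005 with DMSO in GTL-16 cells) limits what can be said of dim genes, whose folds are bounds.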

Other observations

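Of the tests in this part, the list medians under other scalings were chosen after the result was seen. Metabolic, gut and stress genes outside the comparisons above are given by single member and by list. In GTL-16 cells, PHA-665752 lowered TFF1, a mucosal peptide of the stomach (−2.99), and KLF4 (−1.70), and raised TFF3, the intestinal counterpart (1.72). Doxycycline gave −2.95, −1.87 and 2.39. In DiFi cells, gefitinib lowered CEACAM5 (−2.14) and GPA33 (−1.75) and raised MUC13 (0.89). The gut differentiation list went both ways: 5 higher and 4 lower of 19 with PHA-665752 in GTL-16 (camera adjusted p = 0.632, the median turning positive with median centring), 4 and 4 with doxycycline (0.849), and 7 and 4 with gefitinib in DiFi (0.943, median and mean of opposite sign). BMF, a BCL2 family member that promotes cell death, rose with all 3 on-target treatments (1.70, 1.82 and 1.87), while that list had 3 higher and 3 lower of 12 with PHA-665752 (camera adjusted p = 0.941, the median turning positive with the authors' values). CYP1A1, a target of the aryl hydrocarbon receptor, was at least 3.6-fold higher in DiFi cells with gefitinib (2.23 ± 0.16, adjusted p = 1.09e-09). ALDH3A1 (−0.63) and TIPARP (−0.59), of the same list, fell there, and 2 of its 8 genes rose and 5 fell (camera adjusted p = 0.24). One of those that fell was SLC7A5, which the ATF4 list holds too.

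Lysosome and autophagy genes rose in 9 and fell in 1 of 17 cases in DiFi cells with gefitinib (9 and 1 adjusted over the list alone, median 0.34, camera adjusted p = 0.0227, and adjusted p = 0.175 with an estimated correlation), with GABARAPL1 at least 2.58-fold higher and CTSA (1.14) and NEU1 (1.12) higher. With PHA-665752 in GTL-16 cells 5 rose and 2 fell (camera adjusted p = 0.308). Glycolysis and hypoxia genes rose in 5 and fell in 9 of 21 cases there (camera adjusted p = 0.35), with HK2 (2-fold) and SLC2A1, a glucose transporter (−0.92), lower and NDRG1 (1.34) higher. Cholesterol synthesis had 5 higher and 4 lower of 18 genes in DiFi cells with gefitinib (camera adjusted p = 0.668), HMGCS1 at 1.01 among them, and fatty acid synthesis 4 lower of 11 (0.145). Of p53 targets 6 rose and 4 fell of 15 (0.616), with TP53INP1 at 3.09 and DDB2 at −2.05. Interferon response genes had 4 higher and 7 lower of 18 (0.439, the median turning positive with median centring), with CXCL10 at −1.26. Heat shock genes fell in 4 of 14 cases (0.297), nuclear-encoded oxidative phosphorylation genes rose in 2 and fell in 7 of 25 (0.665), and integrin, laminin and adhesion genes rose in 7 and fell in 1 of 15 (0.181), with ITGA2 at 0.82. Receptor tyrosine kinases and feedback adaptors had 5 higher and 5 lower of 15 (0.371, median and mean of opposite sign), with ERRFI1, a feedback inhibitor of EGFR, at −2.16. Immediate early genes had 3 higher and 3 lower of 9 in GTL-16 cells with PHA-665752 (0.237, the median turning positive with median centring), JUN at 1.12 among them. Of 3 leukocyte markers 1 rose and 1 fell in DiFi cells with gefitinib (0.728, the median turning positive with median centring), and of the 18 fibroblast and mesenchymal markers 1 was tested. Counts for gefitinib in DiFi cells include FADS1, IFIT2 and LAMB3, which were detected in neither group. In GTL-16 cells with PHA-665752 or doxycycline none of the lists of these 2 paragraphs passed camera, and fatty acid synthesis with doxycycline came closest (0 higher and 5 lower of 11, ME1 at −1.26, camera adjusted p = 0.0608).

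A hypothesis was set up from the comparison of doxycycline with PHA-665752 in GTL-16 cells: the genes at least 2-fold lower with doxycycline may be ones that gefitinib lowers in DiFi cells as well. Of these 123 genes, 111 (90.2%) were called lower in DiFi cells with gefitinib, against 24.6% of all tested genes and 56% of the genes that doxycycline lowered, with a median log2 change of −1.62 there. G2/M genes made up 30 of the 123 and G1/S genes 4.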
